A study of Mus musculus with 12 samples.

How the data were processed

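RNA sequencing values of sorted splenic GC B cells were analysed for 3 wild-type and 3 T-bet-deficient samples of day 10 after infection. Samples were grouped by their titles, which also give the replicate numbers. The labels name 12 samples, and those of day 15 were not analysed here. Nothing in the labels states outright that each sample came from its own animal, so p-values measure the spread between these samples. Per the labels' protocols, RNA was purified with a column kit and libraries were made with the TruSeq RNA kit.

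The authors deposited raw counts per gene for 27179 Entrez genes, of which 874 rows carry no symbol, and a table of log2 RPKM values per sample for 13361 of these genes. Per the submitters' processing notes, the tools were Subread 1.6.0, featureCounts and limma, and the build was GRCm38 (mm10). Which tool made which file, the annotation, the filters and the strand setting are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart. The deposited log2 RPKM values have nearly the same distribution in every sample, with identical top values in several, and contain no immunoglobulin gene, while the counts contain 260. Coordinates come from the RefSeq annotation of GRCm38.p6, matched by Entrez number for 12956 of the 13377 genes tested. Every sample column of the count table was used.

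Total counts ran from 10649000 to 30185000 per sample, so a gene at 1 CPM has at least 10 reads. No pair of samples agreed within sampling noise (chi-square over degrees of freedom of at least 31.0 over genes with 20 or more reads in a pair), so each was kept as its own replicate. The count and log2 RPKM values of each sample were compared over 9159 genes with a mean above 200 reads. For each gene the difference between log2 CPM and log2 RPKM was centred on its median over samples and then within each sample, and genes more than 1 off were counted. The 2 columns with more than 10% of such genes, those of wild-type replicate 3 and T-bet-deficient replicate 1, are called departing.

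The test fixed before the data were examined was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the 6 count columns, with TMM factors, filterByExpr by group and no covariate. Benjamini-Hochberg adjusted p under 0.05 counted as changed. The alternative fixed for the log2 RPKM values was limma 3.58.1 with a variance trend, leaving out genes under log2 RPKM 0 in every sample, which kept 11644 genes. As the count columns depart from the log2 RPKM values in 2 samples, this alternative is reported beside the first test. The edgeR standard error is the fold change divided by the square root of F. CPM were computed with TMM-scaled library sizes. Other alternatives were DESeq2 1.42.0, RLE factors, total library size, no filter, a stricter filter of 5 CPM in 3 samples, limma-voom, robust dispersion, leaving out immunoglobulin genes, the replicate number as a block, leaving out each replicate, and an absolute log2 fold change of at least 1. Leaving out both departing libraries, and limma without the trend, were added after the data were seen. A fit of all 4 groups together and every day 15 comparison were not run.

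Named genes were chosen by a rule fixed beforehand for the counts, which was carried over to the log2 RPKM values. Tbx21 came first. Then came genes past the threshold whose 3 samples of a group all lie above the 3 of the other, up to 12 in each direction. In the counts a mean of at least 5 CPM in a group was asked for as well. In the log2 RPKM values the only minimum was log2 RPKM of at least 0 in any sample. Immunoglobulin and T cell receptor segments, sex-linked, predicted and pseudogene names were left out. As 1 gene passed in the counts, the 5 genes of lowest p were named as well, Ighg2c being the first of these. From each list up to 4 members of lowest p were named, ranked in log2 RPKM, or in the counts for the heavy chain list. Hbb-bs, Lyz2, Gcsam, Mki67, Sell, Klf2, Ighd, Ighm and Ighg2b were chosen after their values were seen.

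A total of 27 gene lists had been fixed beforehand, and those with at least 3 measured members were tested, 25 in the counts and 24 in log2 RPKM. The test was camera in limma with a preset correlation of 0.01, on log2 CPM or log2 RPKM, adjusted over the lists of a table. Camera with an estimated correlation and fry were alternatives. Shares of heavy chain reads were compared by an exact 2-sided permutation of the 6 samples. Pipelines were tested on simulated data with 200 changed genes each. With the spread of the 4 matching columns edgeR recovered 30 of 100 genes at log2 fold 1 and 100 of 100 at log2 fold 2, with 3 false calls. In simulated log2 RPKM, limma recovered 51 and 87 of 100, with 9 false calls. Figures were drawn with matplotlib 3.10.9.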

Results

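RNA was sequenced from germinal centre (GC) B cells sorted from the spleens of mice infected with Plasmodium berghei ANKA, a rodent malaria parasite. The gate kept CD19-positive, CD138-negative, GL7-positive cells with low CD38. Wild-type cells came from mice carrying the CD23cre transgene, and T-bet-deficient cells came from mice whose floxed Tbx21 alleles were deleted by the same B cell transgene. T-bet, the product of Tbx21, is a transcription factor that drives type 1 immune programmes and switching to the IgG2c isotype (IgG2a in other strains). The labels name 12 samples in 4 groups of 3. Values were analysed for the 6 samples of day 10 after infection, 3 wild-type and 3 T-bet-deficient, and the samples of day 15 were not analysed here. The total count per sample, to 5 digits, was 29545000, 30185000 and 28266000 in wild-type replicates 1 to 3 and 20126000, 26670000 and 10649000 in T-bet-deficient replicates 1 to 3. The comparison asks which genes of GC B cells differ when T-bet is missing, including those that mark the dark and light zones, the compartments between which GC B cells move.

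Tbx21 transcripts separated the groups in both the counts and the log2 RPKM values (log2 of reads corrected for gene length and library size). In the log2 RPKM values Tbx21 stood at 4.28, 4.45 and 4.55 in wild-type replicates 1 to 3, against 1.26, 1.55 and 2.25 in T-bet-deficient replicates 1 to 3. The reads were 1522, 1685 and 1041 in the wild-type count columns and 54, 215 and 144 in the T-bet-deficient ones. The gene lies on chromosome 11 from 97098007 to 97115331 (GRCm38). Its log2 fold change was −2.74 ± 0.25 (SE, n = 3 per group; limma, adjusted p = 0.00624), a 6.68-fold lower level, and T cell markers were lower in the same samples (median log2 fold change −1.79, lowest −2.32). The Tbx21 call was lost without T-bet-deficient replicate 2 (adjusted p = 0.056), with the replicate number as a block (adjusted p = 0.0584) and without the variance trend (adjusted p = 0.0516). Over the 6 count columns the log2 fold change was −2.61 ± 0.54 (edgeR, adjusted p = 0.962; DESeq2, adjusted p = 0.00314). Which exons are floxed is not given in the sources used here, so the remaining reads cannot be assigned to cells that kept the gene.

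**Figure D1:**
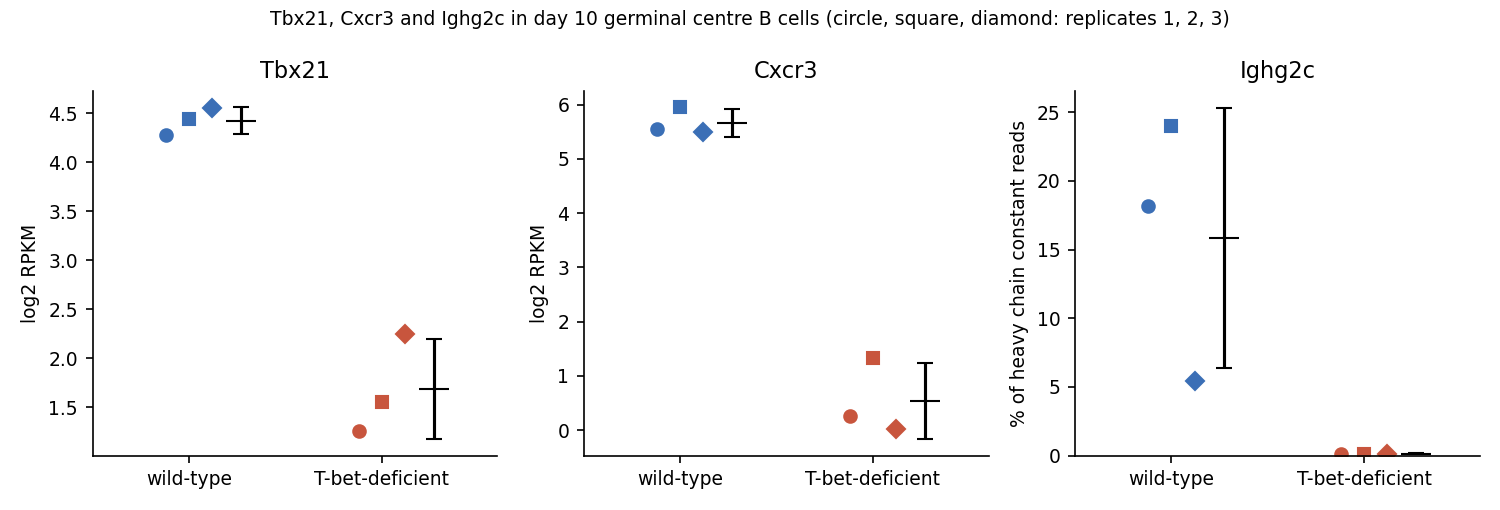
Tbx21 and Cxcr3 (log2 RPKM) and the share of Ighg2c among heavy chain constant reads (percent of counts) in each of the 3 wild-type and 3 T-bet-deficient samples. Symbols mark replicates, and the bar gives the mean and SD. In each panel all 3 T-bet-deficient samples lie below all 3 wild-type samples.

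The count columns labelled wild-type replicate 3 and T-bet-deficient replicate 1 did not match the log2 RPKM values of the same samples. Over 9159 genes, 24.1% and 30.7% of genes lay more than 1 log2 unit off the common relation between the tables in these columns, against at most 0.0109% in the other 4. Both columns held few transcripts of GC B cells. Gcsam, a GC-specific adaptor, had 0.542 and 1.10 CPM (counts scaled by library size) there against 308 to 355 CPM in the other 4, and the proliferation marker Mki67 had 70.3 and 19.7 CPM against 1229 to 1642 CPM. Ighd, the IgD heavy chain of naive B cells, had 2309 and 906 CPM against 17.8 to 78.7 CPM. In the log2 RPKM values the same samples held Gcsam at 6.39 and 6.46, against 6.54 to 6.76 in the other 4. There, wild-type replicate 3 stood apart in markers of other cells, with a mean of the myeloid list of 3.59 log2 RPKM against 0.62 to 1.29, and its correlation across genes with the other samples was 0.870 to 0.926, against 0.937 to 0.968 among the other 5. Tbx21 followed the labels in both tables. Results are therefore given for the 6 count columns, for the log2 RPKM values of the same 6 samples, and for the 4 count columns that match their log2 RPKM values. The last was chosen after the data were seen.

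**Figure D2:**
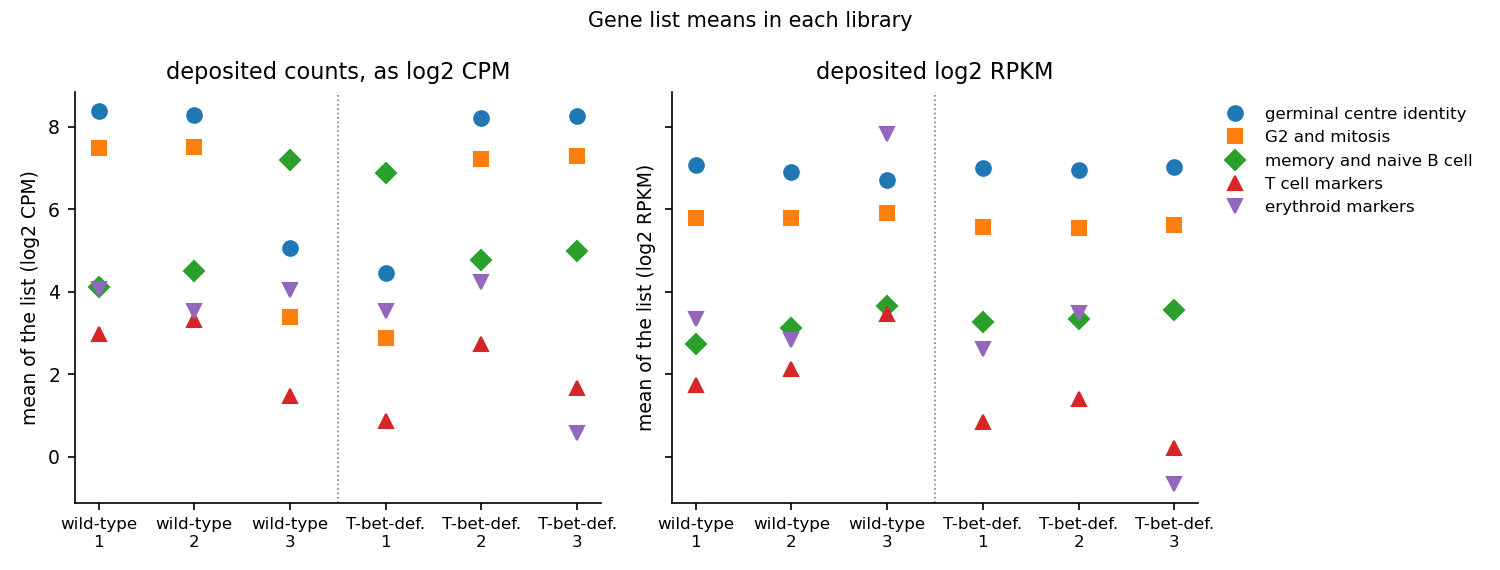
Mean of 5 gene lists in each library, as log2 CPM from the counts (left) and as log2 RPKM (right), with wild-type samples to the left of the dotted line. In the counts, wild-type replicate 3 and T-bet-deficient replicate 1 have low means of the germinal centre identity list (5.07 and 4.44) and high means of the memory and naive list (7.19 and 6.87). In log2 RPKM the erythroid list stands at 7.82 in wild-type replicate 3.

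In the 6 count columns, Ighg2c, the heavy chain constant gene of IgG2c, fell in T-bet-deficient cells and was the only gene of 13377 tested to pass the threshold. Its level was 783 ± 285 CPM in wild-type and 8.15 ± 1.42 CPM in T-bet-deficient samples (SD, n = 3 each), a log2 fold change of −6.59 ± 0.44 (SE; edgeR quasi-likelihood test, adjusted p = 0.0208). The gene lies on chromosome 12 from 113287389 to 113288932. Its neighbour Ighg2b, which is similar in sequence, stood at 791 and 790 CPM in T-bet-deficient replicates 2 and 3, where Ighg2c stood at 8.70 and 9.21 CPM, so few reads of Ighg2b were counted for Ighg2c. The call was lost when any single library other than wild-type replicate 3 was left out, with adjusted p between 0.067 and 0.414, while the fold change stayed between −6.34 and −6.83 over all 6 omissions. It was also lost with the replicate number as a block (adjusted p = 0.686). With the 4 matching columns the log2 fold change was −6.71 ± 0.26 (adjusted p = 4.8e-06).

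As a share of all heavy chain constant reads, Ighg2c made up 15.9 ± 9.46% in wild-type and 0.129 ± 0.0347% in T-bet-deficient count columns (SD, n = 3; exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allows). The lowest wild-type share, in the column labelled replicate 3, was 5.47% (95% Wilson interval 5.38 to 5.56%), and the highest T-bet-deficient share was 0.155% (0.128 to 0.188%). Such intervals cover counting error only. Ighg1 made up 1.44 ± 1.11% and 8.13 ± 7.39% of these reads in the 2 groups (exact permutation p = 0.3). Its share was 1.68, 6.53 and 16.2% in T-bet-deficient replicates 1 to 3, so the last weighs most on that mean. Ighm made up 56.6 ± 10.0% and 71.3 ± 11.4% (exact permutation p = 0.2).

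**Figure D3:**
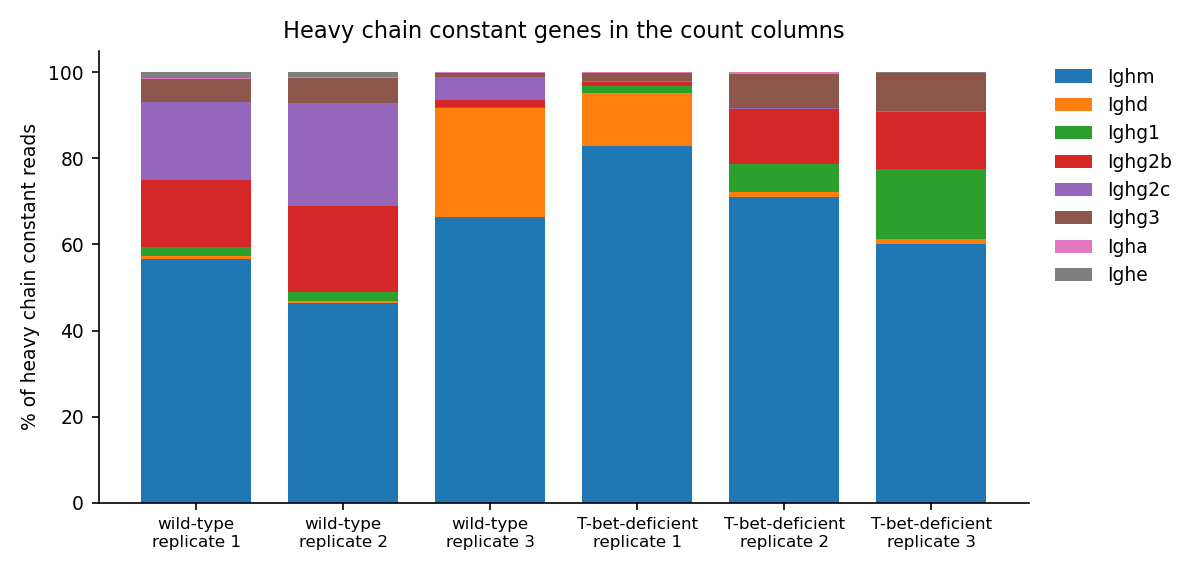
Percent of heavy chain constant reads of each isotype gene in the 6 count columns. Ighg2c (purple) makes up 18.2, 24.0 and 5.47% in wild-type replicates 1 to 3 and at most 0.155% in the T-bet-deficient columns, and the columns of wild-type replicate 3 and T-bet-deficient replicate 1 carry the most Ighd.

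Of the 8 heavy chain constant genes, 1 fell and 7 did not pass in the 6 columns, and the same held adjusted over the list alone. In the 4 matching columns 3 rose and 2 fell. Ighg1 rose by a log2 fold change of 2.88 ± 0.35 (edgeR, adjusted p = 0.0114), Ighg3 by 1.04 ± 0.17 (adjusted p = 0.0317) and Ighd by 1.69 ± 0.22 (adjusted p = 0.013). Ighe fell along with Ighg2c, by a log2 fold change of −4.04 ± 0.28 (adjusted p = 0.000335). Ighg2b showed −0.01 ± 0.19 (adjusted p = 0.992). In the 6 columns the log2 fold changes of Ighg1 (2.92), Ighg3 (1.04) and Ighe (−3.96) had the same sign without passing (adjusted p = 0.962 for each), and that of Ighd was −1.16 ± 1.86. Of the immunoglobulin variable, diversity and joining segments, none of 219 passed in the 6 columns by edgeR, with 7 at an unadjusted p under 0.05, and 1 of 230 passed in the 4 columns.

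The other genes of lowest p in the 6 count columns did not pass the threshold. Cxcr3, the chemokine receptor for interferon-induced ligands and a known T-bet target, stood at 70.8 ± 32.8 CPM in wild-type and 2.39 ± 1.78 CPM in T-bet-deficient columns (SD, n = 3), with a log2 fold change of −4.87 ± 0.71 (edgeR, adjusted p = 0.572). Eps8l1 had a log2 fold change of −3.45 ± 0.49 (adjusted p = 0.561), Tex11 of 5.07 ± 0.72 (adjusted p = 0.561) and Erdr1 of 3.32 ± 0.40 (adjusted p = 0.469). At an unadjusted p under 0.05, 249 genes were higher and 191 lower, where chance alone gives about 669. DESeq2 on the same 6 columns called 11 genes higher and 11 lower, Tbx21, Cxcr3, Eps8l1, Tex11 and Erdr1 among them. Counts were also simulated with the common dispersion of these 6 columns. There edgeR recovered 0 of 100 changes of log2 fold 1 and 5 of 100 of log2 fold 2, with 0 false calls. The simulated libraries did not hold the departure of the 2 columns, so recovery in the real counts can differ.

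In the log2 RPKM values, which hold no immunoglobulin gene, 24 of 11644 genes changed, 13 higher and 11 lower in T-bet-deficient cells (limma with a variance trend). Cxcr3 fell most, from 5.66 ± 0.25 to 0.53 ± 0.70 log2 RPKM (SD, n = 3), a log2 fold change of −5.13 ± 0.33 (SE; adjusted p = 0.00138). It lies on chromosome X from 101731535 to 101734147. Plcd3, a phosphoinositide phospholipase C, fell by a log2 fold change of −5.12 ± 0.47 (adjusted p = 0.00624), and Trp73, a p53 family transcription factor, by −4.87 ± 0.66 (adjusted p = 0.0357). Art3 fell with −3.96 ± 0.52 (adjusted p = 0.0352), Eps8l1 with −3.25 ± 0.30 (adjusted p = 0.00624) and Tox2, an HMG-box transcription factor, with −2.85 ± 0.32 (adjusted p = 0.0255). Smaller falls, between −1.66 and −1.23, were measured for Mns1, Tesk1, Akap12 and Suclg2, a succinate-CoA ligase subunit (adjusted p = 0.0352 for each). With Tbx21 these are all 11 genes that fell. The departing column of wild-type replicate 3 held Plcd3 at 1.08 CPM, Trp73 at 0.325 CPM and Tox2 at 0.361 CPM, against 13.1 to 26.9 CPM in the other wild-type columns.

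Of the 13 genes that rose in the log2 RPKM values, 7 had names within the naming rule, and the other 6 were left out by that rule. Tex11, a gene known from meiosis, rose from −3.75 ± 0.19 to 1.51 ± 0.83 log2 RPKM (SD, n = 3), a log2 fold change of 5.26 ± 0.73 (limma, adjusted p = 0.037). Fcer2a, which encodes the low-affinity IgE receptor CD23, rose by 1.05 ± 0.14 (adjusted p = 0.0352). Its promoter drives the transgene present in both groups. Across the 6 count columns Fcer2a had a log2 fold change of −0.28 ± 0.71, with 1160 CPM in the column labelled wild-type replicate 3. Sh2d1b1 rose by 1.93 ± 0.28 (adjusted p = 0.0442) and Stac2 by 1.29 ± 0.16 (adjusted p = 0.0341). The small nucleolar RNA genes Snord58b, Snord72 and Snord47 rose by 3.95, 2.84 and 2.0, on no more than 103 reads in any count column.

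The 4 matching count columns gave 79 genes higher and 44 lower of 13598 (edgeR). All 24 genes called in log2 RPKM had the same sign there, and 18 were also called, although both comparisons share these 4 samples. The number of log2 RPKM calls depended on single libraries. It was 34 without wild-type replicate 1, 7 without replicate 2 and 38 without replicate 3, and 6, 4 and 6 without T-bet-deficient replicates 1, 2 and 3. With the replicate number as a block it was 2 (Cxcr3 and Eps8l1), without the variance trend it was 10, and without both departing libraries it was 21. Cxcr3 passed under each of these settings.

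**Figure D4:**
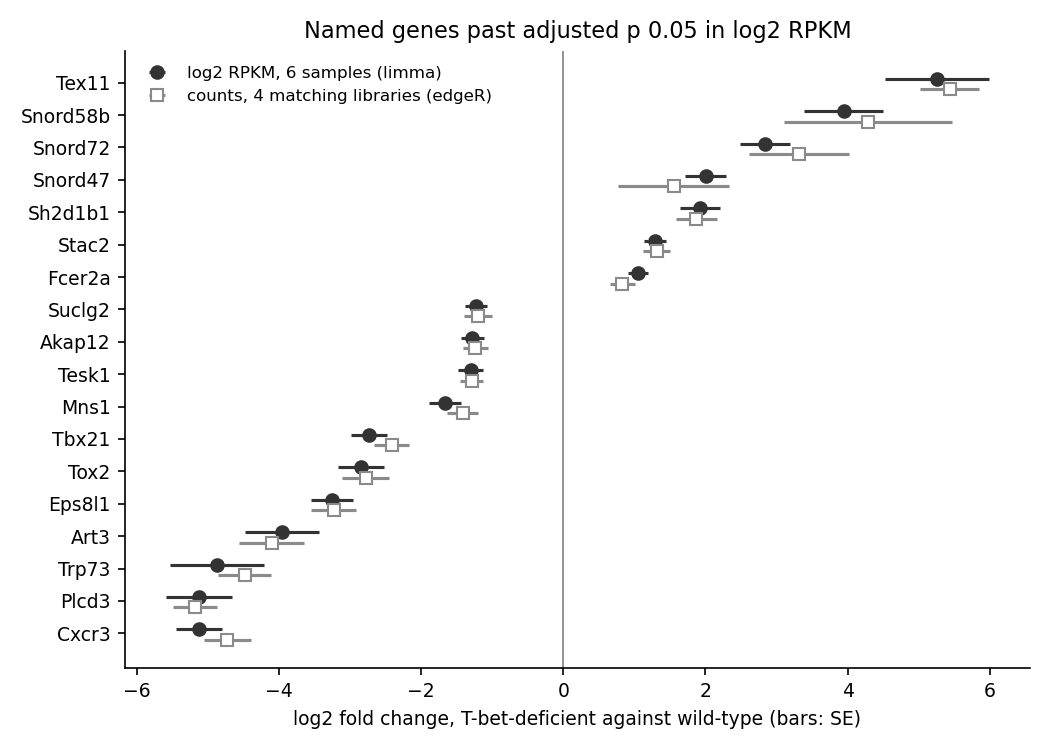
Log2 fold change (T-bet-deficient against wild-type, with SE) of the 18 named genes past adjusted p 0.05 in log2 RPKM (filled, n = 3 per group) and of the same genes in the 4 matching count columns (open, n = 2 per group). All 18 have the same sign in both, from Cxcr3 at −5.13 to Tex11 at 5.26 in log2 RPKM.

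Under camera with the preset correlation, light zone genes were higher as a group in T-bet-deficient cells, while no shift of the dark zone list was found. In log2 RPKM, 22 of 27 measured light zone genes had a positive fold change (median 0.36), and the list passed camera with a preset correlation of 0.01 (adjusted p = 0.000167). With an estimated correlation its adjusted p was 0.402 (unadjusted p = 0.0335). Fcer2a was the light zone gene that rose over all genes tested, and 10 rose adjusted over the list alone. Il4i1, an amino acid oxidase, had a log2 fold change of 1.39 ± 0.24, the costimulatory receptor Cd40 of 1.11 ± 0.27 and the light zone marker Cd83 of 0.91 ± 0.22 (limma, adjusted p = 0.092, 0.167 and 0.167 over all genes). In the 6 count columns the light zone list passed as well (19 of 27 positive, adjusted p = 0.0456, and adjusted p = 0.974 with an estimated correlation). There it was lost without wild-type replicate 1 or 2 or T-bet-deficient replicate 1 or 2 (adjusted p from 0.0681 to 0.588) and with the replicate number as a block (adjusted p = 0.0564), and it passed in the 4 matching columns (adjusted p = 0.00133). Light zone genes stood a median of 0.97 log2 CPM higher in the departing columns. In the 4 matching columns the memory and naive B cell list was higher as well, with a median of 0.42 like that of the light zone list, and so was Ighd (1.69). Of 11 dark zone genes, none passed over all genes, and 2 rose and 3 fell adjusted over the list alone in log2 RPKM (camera adjusted p = 0.39, and 0.935 in the 6 count columns). Those with the lowest p were Polh, a translesion polymerase (−0.62 ± 0.12), Rgs13 (1.08 ± 0.24), Ell3 (0.74 ± 0.22) and the cyclin Ccnd3 (−0.75 ± 0.23).

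Genes of DNA replication and mitosis were lower as groups in the log2 RPKM values under the preset correlation. Of 20 S phase genes, 19 had a negative fold change (median −0.52; camera adjusted p = 5.4e-07, and adjusted p = 0.533 with an estimated correlation). None fell over all genes tested, and 12 fell adjusted over the list alone. The replicative helicase subunits Mcm4 (−0.76 ± 0.18), Mcm3 (−0.69 ± 0.17) and Mcm6 (−0.67 ± 0.15) and the uracil glycosylase Ung (−0.64 ± 0.14) had the lowest p (limma, adjusted p = 0.167 for the Mcm genes and 0.164 for Ung). Of 22 genes of G2 and mitosis, 19 were negative (median −0.21; camera adjusted p = 0.00111, and adjusted p = 0.402 with an estimated correlation). None of these fell over all genes or over the list alone, with Plk1 at −0.68 ± 0.22 and Tpx2 at −0.56 ± 0.13. Of 13 glycolysis genes, 12 were negative (median −0.43; camera adjusted p = 0.00111, and adjusted p = 0.541 with an estimated correlation), and 6 fell adjusted over the list alone, Tpi1 (−0.83 ± 0.25), Pfkl (−0.79 ± 0.24), Eno1 (−0.79 ± 0.26) and Pkm (−0.59 ± 0.19) having the lowest p. In the 6 count columns none of these 3 lists passed (adjusted p = 0.465, 0.67 and 0.118), and all 20 S phase genes were lower in the departing columns (median difference of −2.54 log2 CPM). In the 4 matching columns all 3 passed as lower (adjusted p = 1.5e-06, 0.00133 and 0.000611). The memory and naive B cell list passed as higher in the same 4 columns (camera adjusted p = 0.0156).

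MHC class II presentation genes were higher as a group under the preset correlation. In log2 RPKM 9 of 10 had a positive fold change (median 0.36; camera adjusted p = 0.00441, and adjusted p = 0.541 with an estimated correlation), and 4 rose adjusted over the list alone. Of these genes, H2-DMb1 and H2-Ob had log2 fold changes of 1.36 ± 0.39 and 0.94 ± 0.23 (limma, adjusted p = 0.172 and 0.167). H2-DMb1 stood at 6.23, 6.07 and 4.71 log2 RPKM in wild-type replicates 1 to 3, the last being lowest. Over the omissions of single samples its fold change ranged from 0.88 to 1.64. The list passed camera in log2 RPKM under each omission (adjusted p from 0.000973 to 0.0165). In the 6 count columns all 10 were positive (adjusted p = 0.0456, and adjusted p = 0.974 with an estimated correlation), a call lost in the 4 matching columns (adjusted p = 0.0923). It was also lost without wild-type replicate 1 (adjusted p = 0.564) or 2 (adjusted p = 0.262) and with the replicate number as a block (adjusted p = 0.0895), and its direction reversed without T-bet-deficient replicate 1 (adjusted p = 0.77), whose departing count column had the highest mean of the list (11.1 log2 CPM).

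The list of T-bet-associated B cell genes was lower in the 6 count columns, with 13 of 16 members negative (median −0.77; camera adjusted p = 0.000187, and adjusted p = 0.32 with an estimated correlation). Ighg2c fell over all genes tested, and 2 members fell adjusted over the list alone. The list passed as lower in the 4 matching columns too (adjusted p = 0.0426). In log2 RPKM, where the immunoglobulin members are missing, 8 of 13 were negative and the list did not pass (adjusted p = 0.145). There Cxcr3 fell, and adjusted over the list alone 5 members fell and 2 rose. Il2rb, the interleukin 2 receptor beta chain, had a log2 fold change of −1.37 ± 0.34, while Ifngr2, a subunit of the interferon-gamma receptor (0.75 ± 0.14), and the costimulatory ligand Cd80 (1.19 ± 0.35) lay on the other side (limma, adjusted p = 0.168, 0.107 and 0.175). T cell markers were lower in the same samples (median −1.79), and whether T cells carried the fall of Il2rb was not tested. In the 4 matching columns Il2rb had −0.84 ± 0.24, against a T cell median of −0.89. The homing and confinement receptors, a list that also holds Cxcr3, were lower in the 6 count columns (12 of 16 negative, adjusted p = 0.0456, and adjusted p = 0.974 with an estimated correlation). That call was lost without wild-type replicate 2 or 3 or T-bet-deficient replicate 3 (adjusted p = 0.061, 0.577 and 0.148), with the replicate number as a block (adjusted p = 0.0564) and in the 4 matching columns (adjusted p = 0.361). In log2 RPKM the list did not pass (adjusted p = 0.132).

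By its mean in log2 RPKM, the T cell list was lower in all 3 T-bet-deficient samples than in any wild-type sample, while the erythroid list differed through single samples. In the same values all 16 T cell markers were lower in T-bet-deficient samples (median −1.79; camera adjusted p = 5.4e-07, and adjusted p = 0.541 with an estimated correlation), with 8 falling adjusted over the list alone. The T cell receptor subunit Cd3e stood at 3.10 ± 1.02 in wild-type and 1.11 ± 0.50 in T-bet-deficient samples (SD, n = 3), and Cd4 and Tcf7 had log2 fold changes of −1.88 ± 0.47 and −1.81 ± 0.42. All 12 erythroid markers were negative (median −3.14; adjusted p = 0.00236, and adjusted p = 0.541 with an estimated correlation), led in p by Slc4a1 (−3.90 ± 1.65), and none fell adjusted over the list alone. The erythroid call in log2 RPKM was lost without the departing libraries (adjusted p = 0.0699). The mean of the erythroid list was 3.35, 2.84 and 7.82 log2 RPKM in wild-type replicates 1 to 3 and 2.62, 3.47 and −0.67 in T-bet-deficient replicates 1 to 3, so that wild-type replicate 3 stood apart as high and T-bet-deficient replicate 3 as low. The mean of the T cell list was 1.75, 2.13 and 3.47 in the wild-type samples and 0.83, 1.39 and 0.20 in the T-bet-deficient samples. In wild-type replicate 3 the haemoglobin gene Hbb-bs reached 12.3 log2 RPKM, the myeloid gene Lyz2 7.13 and Cd3e 4.27. In the 6 count columns the T cell and erythroid lists also passed as lower (adjusted p = 0.0205 and 0.0404, and adjusted p = 0.974 for each with an estimated correlation). Their median log2 fold changes were smaller there, at −0.72 and −0.17, and were −0.89 and −0.40 in the 4 matching columns. The T cell call in the counts was lost without wild-type replicate 1 or 2 or T-bet-deficient replicate 1 or 3 (adjusted p = 0.09, 0.46, 0.103 and 0.152), and it passed in the 4 matching columns (adjusted p = 0.000637). The erythroid call in the 6 count columns was lost without wild-type replicate 1, 2 or 3 (adjusted p = 0.09, 0.061 and 0.0776), and its direction reversed without T-bet-deficient replicate 3 (adjusted p = 0.498).

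The remaining lists did not pass camera in log2 RPKM (adjusted p from 0.0556 for NK cell markers to 0.905) or in the 6 count columns (adjusted p from 0.118 for NK cell markers to 0.935). They were germinal centre identity, type I interferon response, interferon-gamma response, plasma cell, memory and naive B cell, B cell receptor signalling, ribosome biogenesis and MYC targets, somatic hypermutation and switching, apoptosis regulators, immediate early and stress genes, and NK cell, myeloid, dendritic cell and stromal markers. In the 4 matching columns 2 of these lists passed. Memory and naive B cell genes were higher (13 of 17 positive, median 0.42; adjusted p = 0.0156), with 1 member rising and 1 falling over all genes, and 7 rising and 1 falling adjusted over the list alone. Ribosome biogenesis and MYC target genes were lower (15 of 19 negative, median −0.25; adjusted p = 0.0143), with none falling over all genes by edgeR and 3 adjusted over the list alone. The heavy chain constant list was tested in the counts only and did not pass (median 0.11, mean −0.89; adjusted p = 0.9). Platelet markers and sex-linked genes had too few members measured. The germinal centre identity list had 8 of 19 genes positive in log2 RPKM (median −0.05, mean 0.09; adjusted p = 0.905). The interferon-gamma response list had a median of 0.06 and a mean of −0.13 (adjusted p = 0.455). Among its genes, Nlrc5 had a log2 fold change of 0.84 ± 0.22 and Cxcl10, which lies within the span of Art3, of −4.17 ± 1.18 (limma, adjusted p = 0.168 and 0.171). The value of Cxcl10 ranged from −5.20 to −2.63 over the omissions of single samples, being −2.63 without T-bet-deficient replicate 1, which stood at −5.62 log2 RPKM, and it was −2.00 ± 0.65 in the 6 and −2.06 ± 0.60 in the 4 count columns (edgeR). Among plasma cell genes, Derl3 had 0.95 ± 0.15 (adjusted p = 0.0592) and Jchain 0.49 ± 0.17 (adjusted p = 0.196). Cd38, whose product was part of the sort gate, had −0.89 ± 0.14 in log2 RPKM (adjusted p = 0.0692) and fell in the 4 matching count columns with −1.02 (edgeR, adjusted p = 0.0291). No list passed with an estimated correlation in either table, and fry called 3 lists in log2 RPKM (light zone, S phase, and G2 and mitosis, adjusted p = 0.0448 each) and none in the counts.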

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

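Leaving out both departing libraries, and limma without the trend, were chosen after the data were seen, and the other settings before. The count of 1 changed gene in the 6 count columns stayed at 1 with RLE factors, total library size, no filter, the stricter filter, limma-voom, robust dispersion and the fold change minimum. It was 22 with DESeq2, 24 with limma on log2 RPKM and 23 with no filter on log2 RPKM, 123 without the 2 departing libraries, and 0 without immunoglobulin genes, which removes the gene called. Leaving out each replicate gave 0 to 1. At an unadjusted p under 0.05, the settings with a count of 0 gave 166 to 812 genes. The log2 RPKM count of 24 was 23 with no filter (20 of them shared), 10 without the trend and 21 without the departing libraries (14 shared), and leaving out each replicate gave 4 to 38. The 6 lists called in the counts became 0 with an estimated correlation and 0 with fry, and 1 to 11 when each replicate was left out. The 7 lists called in log2 RPKM became 0 with an estimated correlation and 3 with fry, and 7 to 12 when each replicate was left out. The cause was not tested for any of these changes other than the removed gene.

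As a block, the replicate number left 0 genes in the counts, 2 in log2 RPKM (Cxcr3 and Eps8l1) and 3 lists in the counts, with 8 lists in log2 RPKM. No pairing of the samples by number was found, but the check cannot exclude one. Deviations of same-numbered samples correlated across genes at −0.628, 0.438 and −0.477 in the counts and at −0.217, −0.0986 and −0.349 in log2 RPKM. The departing count columns, and wild-type replicate 3 in log2 RPKM, stand apart from the other samples and weigh on these values.

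Directions of named genes were kept in log2 RPKM under all settings run, with the call lost in 105 and gained in 7 of the pairs of a gene and a setting, and kept on its side of the threshold in 880. In the counts 158 such pairs stayed, 21 gained a call and 6 lost it. Ighd, which did not pass in the 6 columns, reversed with limma-voom (0.71), the block (1.53), without wild-type replicate 3 (3.98) and without the departing libraries (1.69), and leaving out each replicate gave −3.51 to 3.98. Ighg2b reversed without wild-type replicate 1 (0.08), wild-type replicate 2 (0.37) and T-bet-deficient replicate 1 (0.43), within −0.51 to 0.43 over the 6 omissions. The MHC class II list reversed in the counts without T-bet-deficient replicate 1 (adjusted p = 0.77, the others from 0.00132) and the erythroid list without T-bet-deficient replicate 3 (adjusted p = 0.498, the others from 4.4e-05). The fit of all 4 groups and the day 15 settings were not run. T-bet-deficient replicate 3, at 10649000 reads, has the least precise low counts.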

Other observations

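The tests in this part were chosen after the patterns were seen, the thinning on count columns that were themselves chosen after the data were seen, except the list tests without wild-type replicate 3 and with an estimated correlation, which were among the settings fixed beforehand. The count columns of wild-type replicate 3 and T-bet-deficient replicate 1 also differed from the 4 matching columns in further gene lists. All 24 type I interferon response genes were higher in them (median difference of 1.73 log2 CPM), as were 20 of 24 interferon-gamma response genes (median 1.18). All 22 genes of G2 and mitosis were lower (median −4.25), and 15 of 17 memory and naive genes were higher (median 3.09).

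The departure of these 2 count columns was set against 3 explanations. A step of normalization such as scaling within a library keeps the order of genes. The lower Spearman correlation across genes between length-corrected counts and log2 RPKM was 0.801 in these 2 libraries. It was at least 0.9998 in the other 4, from which the length correction was taken. The value of 0.801 argues against any step that keeps this order, including one that gives all libraries the same distribution. Steps that reorder genes, such as an adjustment of each gene across libraries, were not tested. An exchange of the 2 columns between the groups is argued against by Tbx21, whose CPM was 12.7 times higher in the column labelled wild-type replicate 3. The hypothesis that the columns hold B cells from outside the GC stays open and is consistent with a median difference of −3.50 log2 CPM over the germinal centre identity list, with Sell and Klf2, abundant in resting B cells, at 626 to 996 and 585 to 654 CPM in them against at most 37.4 and 27.6 CPM in the other 4. Whether such cells came from the same animals was not tested.

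The fall of Cxcr3 and Tbx21 was set against T cells in the wild-type samples, since T cells can express both and the T cell list was lower in T-bet-deficient samples. The sort for CD19 would remove T cells, and Cd3e stood at 3.10 log2 RPKM in wild-type samples. The lowest log2 fold change of a T cell marker, −2.32, lay 2.81 above that of Cxcr3, which argues against T cells as its whole source. For Tbx21 that gap was 0.42, with an SE of 0.25 for its fold change, which alone does not decide. As a set, the T cell markers moved apart from Tbx21. Across the wild-type samples the mean of the T cell list ranged over 1.72 log2 RPKM, and Tbx21 over 0.275. In the 4 matching count columns the median T cell log2 fold change was −0.89, against −2.42 ± 0.24 for Tbx21 (edgeR). These values argue against T cells as the whole source of Tbx21, while a part from T cells stays open. Deletion of the floxed Tbx21 alleles in B cells is built into the design of the T-bet-deficient group. How much of the fall of Cxcr3 it accounts for was not tested apart from T cells.

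The higher light zone list and the lower S phase and mitosis lists in log2 RPKM were set against 3 technical explanations. Without wild-type replicate 3, which carried the most transcripts of other cells, 3 of the 3 lists still passed in the same direction, which argues against that library as the cause. Unequal depth cannot be told apart from a shift of the lists, because the depth behind the log2 RPKM of the departing libraries is not known and thinning the 4 matching count columns to 10649000 reads each, after which 3 of the 3 lists passed, tested other values. Correlation between the genes of a list cannot be told apart from a shift of the list, as the lowest adjusted p with an estimated correlation was 0.402. A difference between the genotypes in zone, cell cycle or content of memory and naive B cells stays open. The memory and naive list passed camera as higher in the 4 matching columns (adjusted p = 0.0156) and not in log2 RPKM (adjusted p = 0.355). In those 4 columns 13 of its 17 members were positive, while its member Cd38 fell (−1.02; edgeR, adjusted p = 0.0291).

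With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The counts gave 1 gene in the real split (edgeR) and at most 0 in the others, and log2 RPKM gave 24 (limma) and at most 0. The real split called 6 lists in the counts against at most 14 in the others, and 7 in log2 RPKM against at most 11. Of the 10 splits, with the real one included, 6 called at least as many lists as the real one in the counts. In log2 RPKM the number was 6 as well. The number of lists called therefore does not tell genotype apart from other groupings of the samples, in the counts or in log2 RPKM. The splits of the counts that called 12 to 14 lists were those with both departing columns in the same group. The other splits of the counts, the real one included, called 1 to 6 lists.

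A further hypothesis was that inherited DNA linked to the floxed allele may change genes near Tbx21. Within 10 Mb of Tbx21 on chromosome 11, 2 of 229 genes tested in log2 RPKM were called (Stac2 at 0.939 Mb and Plcd3 at 5.97 Mb), against 17 called of 11330 with a position (Fisher's exact p = 0.0453, 2-sided). Counting called genes without a position as lying elsewhere gave Fisher's exact p = 0.0744, and the 4 matching count columns gave 5 of 258 and Fisher's exact p = 0.0758, or 0.0827 when counted in that way, so the hypothesis is left undecided. On chromosome X, Tex11 and Cxcr3, the genes with the largest rise and the largest fall in log2 RPKM among those named, start 0.893 Mb apart, and none of the 10 genes tested between them was called by limma, with 3 at an unadjusted p under 0.05 and a largest absolute log2 fold change of 2.61.

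Small nucleolar RNA genes were 3 of the 24 genes called in log2 RPKM and 45 of the 11644 tested (Fisher's exact p = 0.000103, 2-sided). Of the 45, 41 had a positive fold change (median 1.58). A candidate explanation is that such short genes, measured on few reads, were captured apart from longer ones in these libraries. In the 4 matching count columns none of 52 was called by edgeR, with 11 at an unadjusted p under 0.05 and a median log2 fold change of 1.09.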
